A study of Homo sapiens with 7 samples.

How the data were processed

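RNA of early-passage human lung fibroblast cultures, extracted with TRIzol, was labelled with biotin as cRNA and hybridized to CodeLink UniSet Human I arrays, one-colour oligonucleotide arrays stained with streptavidin-Alexa dye. There were 3 arrays of cultures from lungs of normal histology and 4 of cultures from explanted lungs with usual interstitial pneumonia (UIP), with 1 array per culture. A further UIP culture that the series design counts was not analysed here. Replicates were numbered within each group in the order of the sample list, and no culture had more than 1 array. The header of UIP replicate 4 marks a rescan. No paired analysis was possible because the labels give no link between normal and UIP cultures.

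Per the file headers, CodeLink System Software 2.2.25 quantified the spots, wrote a raw intensity and quality flags, and divided the raw intensity by the array median with a threshold trim of 20% to give the normalized intensity. The deposited raw intensity reached below 0, so background had been subtracted before deposit, and how it was subtracted is not described in the headers. The deposited series matrix held the same intensity as the normalized column, on a linear scale without centring, with a largest difference of 4.92e-08 and column medians of 0.926 to 0.951. Each array had 10458 probes, of which 9970 were discovery probes and 300 negative controls.

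Quantile normalization across the 7 arrays was applied to the raw intensity of the discovery probes. Values under 7.51, the median over arrays of the mean negative control, were raised to it, and log2 was taken. Values that the software had given a poor or a manufacturer-removed flag were treated as missing. A probe was kept if the software called it above threshold on at least 3 of the 7 arrays. Gene symbols came from the platform annotation for 8790 discovery probes, from the accession for 317 and from the description for 96. There were 13 probes of several genes and 767 unnamed probes. Another 13 probes, of XIST or Y-linked genes, were left out of every result. The 9285 probes kept gave 8914 tested items, 8204 of them named genes and the rest single unnamed probes, and the 358 genes with several probes were averaged on the log2 scale.

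UIP minus normal was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 8914 items at 0.05. The labels state another criterion, groups that do not overlap and an unadjusted t-test p under 0.05, and the number of genes meeting it was counted on the log2 values and compared with the same count in the other splits of the arrays. The 23 gene lists, with 795 distinct genes, were fixed before the data were examined, as were the tests and most of the other settings tried. The array carried probes for 533 of the 795 genes, and 507 were tested. Lists were tested with limma's camera, which asks whether a list's genes shifted relative to the other genes, with a preset correlation between genes of 0.01, over the 8160 items with values on all 7 arrays. Lists with at least 5 such genes were tested, which left 22 of the 23. Camera with an estimated correlation, fry and an exact permutation test of the list's mean log2 difference over the 35 splits of 7 arrays into 3 and 4 stood beside it. The smallest exact p that the 35 splits allow is 0.0286. The exact p is given without adjustment, and adjusted over the 22 lists it was 0.157 or higher for every list.

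Genes were named by a rule fixed before the data were examined. It took, among genes whose groups did not overlap, the 10 of each direction that passed the adjusted threshold with the largest difference, filled with those of the smallest p where fewer passed, which was so for all 20, of which 19 are described. It also took WNT5A, whatever its value, because the study's group later reported on it, as well as up to 4 members of each list by smallest p, and COL1A1, COL3A1, FN1, ACTA2 and TAGLN. Of the members, 4 are given for each list that was called and 1 for most of the other lists. COL3A1, FN1 and ACTA2 had no named probe and were not measured here.

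Print lots of slides were defined after the data were examined, from the overlap of the spots that the manufacturer had removed, and they use no expression value. Other settings chosen before the data were examined were the software's normalized intensity, the series matrix, cyclic loess, a floor 2 times and 0.5 times as high, no filter and a filter on all 7 arrays, the brightest probe per gene, flagged values kept, eBayes with trend and robust, array weights, a slide batch as a block where the files give one (the print lots were used for it), each array left out, the t-test and its Welch form, linear intensity, estimated correlation, fry and lists without shared genes. Settings chosen after the data were examined were normexp fitted with negative controls, fits within each lot, the lot as a random block, the good flag as the filter, genes with an Entrez ID on linear values, probe levels aligned before averaging, and normal replicates 1 and 2 left out together. On simulated data with the same spread, made from 8160 genes of which 200 were changed, the limma fit found 41.8% of genes changed 2-fold, 91.0% of genes changed 4-fold and 92.4% of genes changed 8-fold, called 2 unchanged genes, and called 0 when no gene was changed. A simulated list shifted by 0.5 was called with the preset correlation and not with the estimated one. Every gene was simulated independently of the others. The simulations therefore cannot show how the limma fit or either correlation behaves on genes that vary together.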

Results

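Gene expression was measured in primary fibroblasts, the matrix-producing cells of connective tissue, grown for early passages from human lungs. Of the 7 arrays, 3 held cultures from lungs of normal histology (normal) and 4 held cultures from explanted lungs with usual interstitial pneumonia (UIP), a tissue pattern of progressive lung scarring. The labels give each culture its own donor, so standard deviations, single-gene p-values and exact permutation p-values reflect the spread between cultures of separate donors. Camera's p-values at the preset correlation compare a list's genes with the other genes and do not measure that spread. Between 89.4% and 92.8% of the 9970 discovery probes were above the software's threshold on an array, 91.8% to 92.8% in normal and 89.4% to 91.8% in UIP. The deposited raw intensity had a median of 186 to 282 per array, which was 22.2 to 32.5 times the mean of the negative controls, and the number of arrays limits the precision. Slides were clustered into 2 groups, called print lots here, by the spots their manufacturer had removed, a grouping made after the data were examined. The number of groups was set at 2, and no label names a print lot. Lot A held normal replicates 2 and 3 and UIP replicates 1 and 2, and lot B held normal replicate 1 and UIP replicates 3 and 4. Arrays shared 61.9% to 80.5% of removed spots within a lot and 33.1% to 37.0% between lots. The groups were formed from this overlap, so it describes them and is no separate support for them. Values within each lot and with the lot as a block stand beside the results. Lot B has 1 normal array, which is assumed to vary like the UIP arrays.

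The comparison of UIP with normal fibroblasts asked which genes were expressed at different levels in fibroblasts of scarred lung. Normal cultures carried far more mRNA of CD36, a scavenger receptor and fatty acid transporter, than UIP cultures. Its log2 intensity was 13.46 ± 0.69 (SD, n = 3) in normal and 8.35 ± 1.37 (SD, n = 4) in UIP, which is 34.5-fold lower in UIP. Whether this difference lies in the fibroblasts or in other cells of the cultures was not tested. MSR1, a macrophage scavenger receptor, was above threshold on 3 of 3 normal arrays and 0 of 4 UIP arrays, at least 7.30-fold lower in UIP. UIP cultures carried more mRNA of SULF2, a secreted enzyme that removes sulfate from heparan sulfate (log2 difference 2.81). They also carried more of IGFBP5, a secreted binding protein of insulin-like growth factors (4.20-fold). None of these differences passed the test over all genes: limma called 0 of 8914 items at an adjusted p under 0.05, with 551 at an unadjusted p under 0.05 (300 higher and 251 lower in UIP) where 445.7 are expected by chance. Of the 35 splits of the 7 arrays into 3 and 4, 5 gave at least 551 such items, and the highest other count was 1032. Without normal replicate 2, 346 items had an unadjusted p under 0.05. The study's own kind of test, the methods' t-test for each gene, gave 474 items at an unadjusted p under 0.05 and its unequal-variance form 366, and both gave 0 after adjustment.

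The 10 genes higher in UIP with the smallest p and no overlap between groups had adjusted p of 0.258 to 0.504. SULF2 had a log2 intensity of 7.80 ± 1.38 (SD, n = 3) in normal and 10.60 ± 0.50 (SD, n = 4) in UIP, and IGFBP5 of 8.09 ± 0.42 (SD, n = 3) in normal and 10.16 ± 0.72 (SD, n = 4) in UIP. SPOCK1, a secreted proteoglycan, differed by 1.59 ± 0.33 (log2 difference and its SE), and FGFR2, a receptor of fibroblast growth factors, was above threshold on 0 of 3 normal and 4 of 4 UIP arrays, at least 1.75-fold higher in UIP. LIMS2, an adaptor protein of integrin adhesions, differed by 1.38 ± 0.28 and KANK1, a regulator of the actin skeleton, by 1.62 ± 0.25. SLC2A11, a sugar transporter, differed by 2.33 ± 0.47, while C2CD2 differed by 1.04 ± 0.15 and ZNF853 by 1.30 ± 0.23. The same 10 held WNT5A, a secreted Wnt ligand that acts largely without beta-catenin.

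WNT5A was named before the data were examined here, because the study's group later reported on it. Whether that report used these arrays is not known here, so the choice may not be independent of these data. Its log2 intensity was 8.10 ± 0.20 (SD, n = 3) in normal and 9.07 ± 0.28 (SD, n = 4) in UIP, a difference of 0.97 ± 0.20 and 1.96-fold higher in UIP. All 4 UIP arrays lay above all 3 normal arrays, the two-sided exact permutation p was 0.0286, the smallest that the 35 splits allow, and the limma adjusted p was 0.504, which is not past the threshold. Within print lots the WNT5A difference was 0.63 in lot A and 1.44 in lot B, and with the lot as a block it was 0.95 (adjusted p = 0.498, and 0.185 to 1 over the settings tried).

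The 9 genes described here as lower in UIP had adjusted p of 0.106 to 0.504. MSR1 had a log2 intensity of 6.74 ± 0.90 (SD, n = 3) in normal and 3.59 ± 0.12 (SD, n = 4) in UIP. The log2 difference of CD36 was -5.11 ± 0.70 (adjusted p = 0.218). Immune cell genes were FCER1G, a signalling chain of antibody receptors, which differed by -1.32 ± 0.23, and HCLS1, a cytoskeletal protein of blood cells, which was above threshold on 3 of 3 normal and 0 of 4 UIP arrays and was at least 1.67-fold lower in UIP. ENPP2, which encodes autotaxin, the secreted enzyme that makes lysophosphatidic acid, differed by -2.35 ± 0.43, and NTNG1, a membrane-anchored netrin, by -1.44 ± 0.24. GGH, a folate hydrolase, differed by -1.40 ± 0.28, IGFN1 by -3.08 ± 0.56, and EPB41L3, a membrane skeleton protein measured on 3 UIP arrays, by -1.54 ± 0.29. With the lot as a block the adjusted p of the 19 genes was 0.280 to 0.498.

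**Figure D1:**
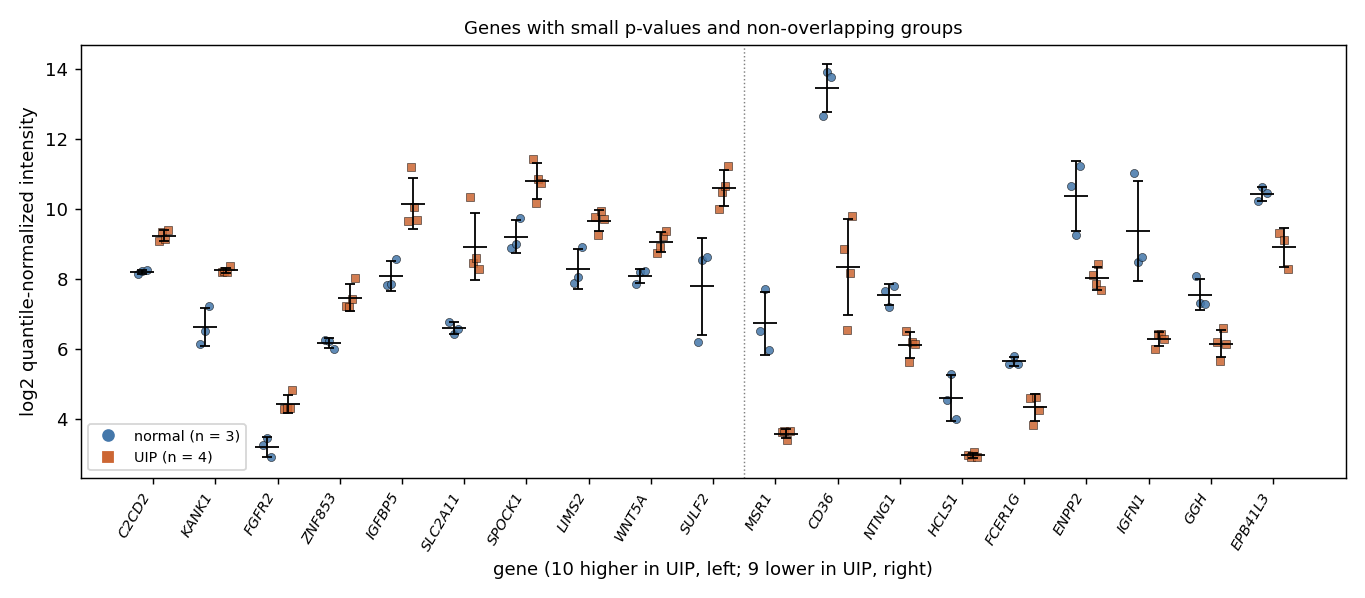
Log2 quantile-normalized intensity (vertical axis) of 19 genes with non-overlapping groups and small p, for 3 normal arrays (blue circles) and 4 UIP arrays (orange squares, 3 for EPB41L3). Horizontal lines are means and bars are 1 SD; CD36 lies at 13.46 in normal and 8.35 in UIP, and no gene passed the adjusted threshold.

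By the criterion that the labels state, non-overlapping groups and the methods' t-test p under 0.05, 395 items differed, 226 higher and 169 lower in UIP. With cyclic loess normalization the balance of directions flipped to 188 higher and 208 lower, and with the software's own values it was 191 and 187. Across the other splits of the 7 arrays into 3 and 4 the median count was 343. Groups did not overlap for 646 items, 7.25% of those tested, where chance gives 5.71% for an item with values on all 7 arrays. Of the 35 splits, 11 gave at least 646 such items, and the median of the other splits was 601, so no excess is shown. The labels report 236 of 8396 genes with an Entrez ID on the authors' full set of samples, and the same criterion on linear software values gave 328 of 8317 such genes here. Leaving out normal replicate 3 raised the count from 395 to 647.

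Of 22 gene lists tested with camera at a preset correlation, 11 shifted relative to the other genes, 6 up and 5 down in UIP. With an estimated correlation 0 lists passed (smallest adjusted p = 0.161), and 0 passed with fry (0.0610). That correlation ran from -0.05 for lipid-storing genes to 0.59 for interferon genes, against the preset 0.01. It lay below the preset for the lipid-storing, leukocyte (-0.007) and smooth muscle (-0.03) lists, whose unadjusted camera p rose all the same. For leukocyte markers it rose from 5.25e-05 to 0.00731. A larger correlation is therefore not the reason that these lists were lost. The simulated list of independent genes was also lost with the estimated correlation. In the exact permutation test the smallest p adjusted over the lists was 0.157. No member of any list passed over all genes. Adjusted over the list alone, FGFR2, IGFBP5, IGF1 and F2R passed among growth factors and receptors, MSR1 and FCER1G among leukocyte markers, PLN and LMOD1 among smooth muscle markers, WNT5A in Wnt signalling and CD36 in the lipid-storing list. In lists that were not called, those that passed in this way included SOD2 and TEK. The number of lists called was 6 without normal replicate 1 (2 up and 4 down), 7 without normal replicate 2 (5 up and 2 down) and 10 with the lot as a block (6 up and 4 down). It was 5 within lot A (1 up and 4 down, 4 of them among the 11). Lot B has 1 normal array, so lists called there are not counted, and calls lost there say little for the same reason. There the cytokine list, called lower in UIP over all arrays, had a mean of 0.42.

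Genes of the extracellular matrix and of contraction were higher in UIP on average. The list of collagens and matrix proteins had 28 of 32 measured genes higher in UIP, with a mean log2 difference of 0.50 (camera adjusted p = 0.000338, and adjusted p = 0.539 with an estimated correlation). That mean was 0.19 in lot A, 0.94 in lot B and 0.48 with the lot as a block, and its exact permutation p was 0.171. The collagen call was lost within lot A (adjusted p = 0.733), and without normal replicate 3 the mean was 0.77. UIP replicate 2 had a list mean of -0.50, against 0.35 to 0.50 on the other 3 UIP arrays. Normal replicates 1, 2 and 3 had -0.53, -0.56 and 0.27, so the groups overlapped. With normal replicates 1 and 2 left out together the collagen mean difference was -0.05. BGN, the proteoglycan biglycan, differed by 2.04 ± 0.72 (1.16 without normal replicate 2), COL8A1 by 1.31 ± 0.46, COL6A2 by 0.88 ± 0.33 and COL18A1 by 0.68 ± 0.20. COL1A1, the main fibrillar collagen chain, differed by 0.03 ± 0.18, with -0.22 in lot A and 0.43 in lot B, and by -0.00427 with cyclic loess. Myofibroblast and contractile genes had 14 of 16 measured genes higher, a mean of 0.40 (camera adjusted p = 0.000338, and adjusted p = 0.312 with an estimated correlation), and 0.39 in lot A, 0.32 in lot B and 0.37 with the lot as a block. Their exact permutation p was 0.0571, their mean without normal replicate 2 was 0.22, and their call was lost within lot B (adjusted p = 0.0560). LMOD1, which nucleates actin filaments in smooth muscle, differed by 0.96 ± 0.27, VCL, the adhesion protein vinculin, by 0.55 ± 0.18, and TAGLN, an actin-binding protein of smooth muscle, by 0.64 ± 0.21 over 3 normal and 3 UIP arrays. FHL2 had values on 1 normal and 3 UIP arrays and differed by 1.10.

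Smooth muscle and pericyte markers, a list for another cell type that shares LMOD1 with the contractile genes, had 8 of 11 measured genes higher and a mean of 0.45 (camera adjusted p = 0.0192, and adjusted p = 0.312 with an estimated correlation). The mean was 0.37 in lot A, 0.61 in lot B and 0.47 with the lot as a block, and all 4 UIP arrays lay above all 3 normal arrays (exact permutation p = 0.0286). PLN, the calcium pump regulator phospholamban, differed by 1.99 ± 0.49, SYNPO2 by 1.09 ± 0.49 (0.62 without normal replicate 1 and 0.71 without UIP replicate 2) and HSPB7 by 0.48 ± 0.20. The call was lost without normal replicate 1 (mean 0.37, adjusted p = 0.150) and without UIP replicate 2 (0.41, adjusted p = 0.0593). It was lost as well without the genes shared with another list (adjusted p = 0.0847), with array weights (0.0835), with no filter on dim probes (0.0501) and within lot A (0.213).

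Signalling lists were also higher in UIP on average. Growth factors and receptors had 21 of 33 measured genes higher and a mean of 0.31 (camera adjusted p = 0.0146, and adjusted p = 0.313 with an estimated correlation), with 0.11 in lot A, 0.64 in lot B and 0.32 with the lot as a block, and an exact permutation p of 0.0857. IGF1, insulin-like growth factor 1, differed by 2.23 ± 0.54, a 4.70-fold higher level in UIP, and F2R, a thrombin receptor, by 0.76 ± 0.21. That call was lost without normal replicate 1 (mean 0.20, adjusted p = 0.242) and without UIP replicate 4 (0.27, adjusted p = 0.0509), and with a filter on all 7 arrays (0.26, adjusted p = 0.0769). Wnt signalling genes had 27 of 36 measured genes higher and a mean of 0.28 (camera adjusted p = 0.0126, and adjusted p = 0.312 with an estimated correlation), with 0.16 in lot A, 0.47 in lot B and 0.28 with the lot as a block, and an exact permutation p of 0.0286. Besides WNT5A, CCN5, a secreted Wnt-induced protein, differed by 2.07 ± 0.61 over 3 UIP arrays, LEF1, a transcription factor of the pathway, by 1.84 ± 0.74 and the receptor FZD7 by 0.85 ± 0.35 (0.53 without normal replicate 2 and 1.28 without normal replicate 3). The Wnt call was lost without normal replicate 1 (mean 0.23, adjusted p = 0.150) and without normal replicate 2 (0.26, adjusted p = 0.0548). TGF-beta and BMP signalling genes had 22 of 30 measured genes higher and a mean of 0.27 (camera adjusted p = 0.0126, and adjusted p = 0.313 with an estimated correlation), with 0.08 in lot A, 0.59 in lot B and 0.29 with the lot as a block, and an exact permutation p of 0.171. BMP4 differed by 1.46 ± 0.61, ID4, a target of BMP signals, by 1.07 ± 0.33, and LTBP2 and LTBP1, matrix proteins of the TGF-beta binding family, by 0.56 ± 0.21 and 0.56 ± 0.27 (LTBP1 0.32 without UIP replicate 2). Without normal replicate 1 the TGF-beta mean was 0.13 and its call was lost (adjusted p = 0.157), and without normal replicate 3 the mean was 0.44. Within lot A the calls of growth factors (adjusted p = 0.591), Wnt (0.213) and TGF-beta genes (0.399) were all lost, and with array weights too (0.0756, 0.0657 and 0.0657).

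**Figure D2:**
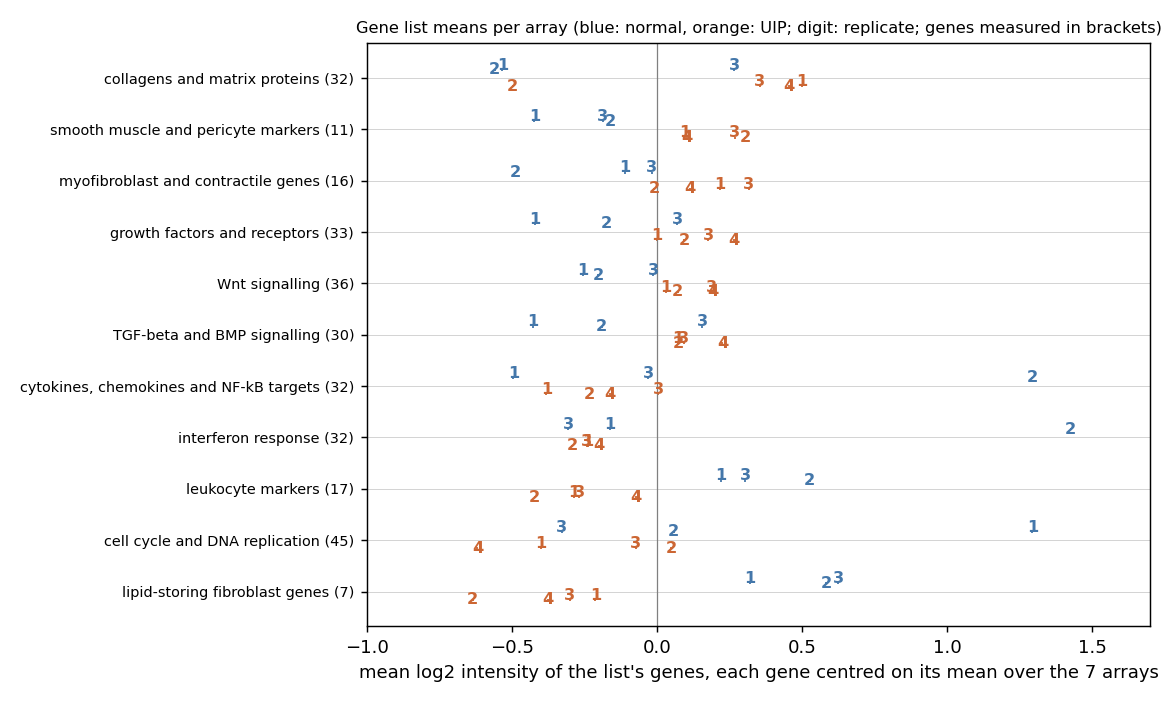
Mean log2 intensity of each list's genes per array, each gene centred on its mean over the 7 arrays (horizontal axis), for the 11 lists that camera called with the preset correlation, with 3 normal arrays in blue and 4 UIP arrays in orange. Digits give the replicate; normal replicate 1 stands at 1.29 in the cell cycle list and normal replicate 2 at 1.43 in the interferon list.

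Cell cycle and DNA replication genes had 43 of 45 measured genes lower in UIP and a mean log2 difference of -0.62 (camera adjusted p = 8.46e-09, and adjusted p = 0.430 with an estimated correlation). CDC25C, a phosphatase that starts mitosis, differed by -1.44 ± 0.46, CDC6, which loads the DNA replication machinery, by -0.51 ± 0.19, and CKS2 by -1.02 ± 0.38 (-0.57 without normal replicate 1). CDC45, which fires that machinery, was above threshold on 3 of 3 normal and 3 of 4 UIP arrays. The mean of this list was -0.05 in lot A, -1.66 in lot B and -0.69 with the lot as a block. Normal replicate 1 had a list mean of 1.29, against -0.62 to 0.06 on the other 6 arrays, and without it the difference was -0.14 (adjusted p = 0.138), so the call rests on that array. The call was lost within lot A (adjusted p = 0.657), and without normal replicate 3 the mean was -0.94. The exact permutation p over all arrays was 0.200.

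Interferon response genes had 27 of 32 measured genes lower and a mean of -0.57 (camera adjusted p = 0.000156, and adjusted p = 0.539 with an estimated correlation). IFIT1, an RNA-binding antiviral protein, differed by -1.35 ± 0.48, IFI44 by -1.08 ± 0.51, the ubiquitin-like ISG15 by -1.06 ± 0.56 and PSMB9, an immunoproteasome subunit, by -0.997 ± 0.54. Without normal replicate 2 these genes differed by -0.86 (IFIT1), -0.43 (IFI44), -0.34 (ISG15) and -0.25 (PSMB9, -1.61 without normal replicate 3). The interferon mean was -0.83 in lot A, -0.04 in lot B and -0.53 with the lot as a block, and its call was lost within lot B (adjusted p = 0.914). Cytokines, chemokines and NF-kB targets had 23 of 32 measured genes lower and a mean of -0.46 (camera adjusted p = 0.0126, and adjusted p = 0.539 with an estimated correlation), with -0.94 in lot A, 0.42 in lot B and -0.43 with the lot as a block, where lot A holds normal replicate 2 and lot B has 1 normal array. IL13RA2, a decoy receptor of interleukin 13, differed by -1.60 ± 0.54, TNFAIP3, an inhibitor of NF-kB, by -1.15 ± 0.43 (-0.55 without normal replicate 2), PTGES, a prostaglandin E synthase, by -1.24 ± 0.65 (-0.66 without normal replicate 2 and -0.77 without UIP replicate 2) and SOD2, a mitochondrial superoxide dismutase, by -0.88 ± 0.22. Normal replicate 2 had list means of 1.43 and 1.29 in these 2 lists. Without it the interferon difference was 0.000772 (adjusted p = 0.766) and the cytokine difference 0.03 (adjusted p = 0.945), so neither call was kept. Without normal replicate 3 the interferon mean was -0.92, and without normal replicate 1 the cytokine mean was -0.85. The exact permutation p was 0.200 for interferon and 0.457 for cytokine genes.

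Leukocyte markers, another list for cells other than fibroblasts, had 13 of 17 measured genes lower in UIP and a mean of -0.61 (camera adjusted p = 0.000338, and adjusted p = 0.161 with an estimated correlation). The leukocyte mean was -0.77 in lot A, -0.39 in lot B and -0.62 with the lot as a block, all 4 UIP arrays lay below all 3 normal arrays (exact permutation p = 0.0286), and the call was kept with each array left out and ended within lot B alone (adjusted p = 0.114). Without normal replicate 2 the mean was -0.39 (adjusted p = 0.0186). Besides MSR1 and FCER1G, LAPTM5, a lysosomal protein of blood cells, differed by -2.04 ± 0.70 (-1.19 without normal replicate 2), and TYROBP, a signalling adaptor of myeloid cells, was above threshold on 3 of 3 normal and 1 of 4 UIP arrays. The other 13 members differed by -0.78 to 0.39, and the list's median was -0.34. Lipid-storing fibroblast genes had 6 of 7 measured genes lower and a mean of -0.89 (camera adjusted p = 0.0422, and adjusted p = 0.312 with an estimated correlation), with the largest difference in CD36 and a list median of -0.24. In the mean of this list, on which CD36 weighs heavily, all 4 UIP arrays lay below all 3 normal arrays (exact permutation p = 0.0286). PPARG, a transcription factor of fat cells, differed by -0.51 ± 0.25 (-0.33 without UIP replicate 1), ADIRF by -0.57 ± 0.43 (-0.21 without normal replicate 2 and -0.21 without UIP replicate 4) and CEBPA by 0.38 ± 0.17 (0.25 without normal replicate 2). The lipid mean was -1.03 in lot A, -0.66 in lot B and -0.88 with the lot as a block, where its call ended (adjusted p = 0.0990, 0.267 and 0.0642). It ended too without normal replicate 1 (mean -0.995, adjusted p = 0.0863), normal replicate 2 (-0.85, 0.0511), normal replicate 3 (-0.83, 0.166), UIP replicate 2 (-0.80, 0.0593) or UIP replicate 4 (-0.89, 0.0509), with no filter on dim probes (-0.75, 0.123) and with normexp on negative controls (-0.88, 0.0574).

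The other 11 lists tested were not called, with adjusted p from 0.110 for apoptosis regulators (mean -0.16; CASP4, an inflammatory caspase, -0.87 ± 0.33) upward. Mean log2 differences were -0.13 for antioxidant and metallothionein genes, -0.06 for cytosolic ribosomal proteins (RPL11 -0.42 ± 0.19), 0.08 for the unfolded protein response (VLDLR 0.78 ± 0.39, 0.30 without normal replicate 1 and 1.19 without normal replicate 3) and 0.02 for p53 targets and senescence (PLK2 0.32 ± 0.20). Epithelial markers had a mean of -0.01 (CLDN4 above threshold on 3 of 3 normal and 3 of 4 UIP arrays). Endothelial markers had a mean of 0.10 and a median of -0.01, which differ in sign, and TEK, an angiopoietin receptor, differed by 0.91 ± 0.20. Mean and camera direction differed in sign for hypoxia and glycolysis (mean 0.03, camera down; ERO1A -0.82 ± 0.33), matrix remodelling enzymes (0.07, camera down; the metalloproteinase MMP11 1.30 ± 0.38) and positional transcription factors (0.09, camera down). They also differed for cholesterol synthesis (-0.02, camera up), where the averaged value of SREBF1 differed by 1.01 mainly because its brighter probe had no value in normal replicate 2. It was 0.13 without that array and 0.33 with the probe levels aligned before averaging, and its probes, taken singly, differed by -0.22 and 0.60. Without UIP replicate 3 antioxidant genes (-0.25, adjusted p = 0.0104) and apoptosis regulators (-0.18, 0.0460) were called lower in UIP, and without normal replicate 1 hypoxia genes were (-0.18, 0.0337). The mean of 7 of the 11 lists changed sign with 1 array left out, to between -0.07 and 0.06 where no call was made: ribosomal and matrix remodelling genes (normal replicate 1), p53 targets (normal replicate 1 or UIP replicate 2), hypoxia genes (UIP replicate 3 or 4, besides normal replicate 1), epithelial markers (normal replicate 2, UIP replicate 2 or 4), positional factors (normal replicate 2) and cholesterol synthesis (normal replicate 1 or 2, or UIP replicate 4). The other 4 means moved by over 1.5 times: apoptosis regulators to -0.06 (without normal replicate 2), antioxidant genes to -0.06 (without UIP replicate 4), endothelial markers to 0.00158 (without normal replicate 1) and the unfolded protein response to 0.00277 or 0.20 (without normal replicate 2 or 3). No direction is read from any of the 11. Mesothelial markers had 5 measured genes, 4 of them on all 7 arrays, and were not tested as a list; CALB2, the calcium-binding protein calretinin, differed by 1.98 ± 0.53.

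For KANK1, FGFR2, SLC2A11, MSR1, FZD7, SOD2, TYROBP, SYNPO2, ADIRF and the TGF-beta list 1 UIP array stood apart from the other 3 relative to their range. The gap itself was small for some, such as KANK1, at 8.37 against 8.20 to 8.23 on the log2 scale. Pearson's r across 8160 genes, which are not independent replicates and whose differing levels alone keep r high, was 0.939 (normal replicates 1 and 2) to 0.962 between normal arrays, 0.956 to 0.973 between UIP arrays and 0.941 to 0.974 between groups. The mean distance between arrays of different groups exceeded that within groups by 0.0418 on the log2 scale (exact permutation p = 0.0571 over the 35 splits). It did not exceed the distance among normal arrays: it was 0.650 between groups, 0.660 among normal arrays and 0.582 among UIP arrays. Normal replicate 3 had r of 0.963 to 0.974 with the UIP arrays, above its r of 0.956 and 0.962 with normal replicates 1 and 2.

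**Figure D3:**
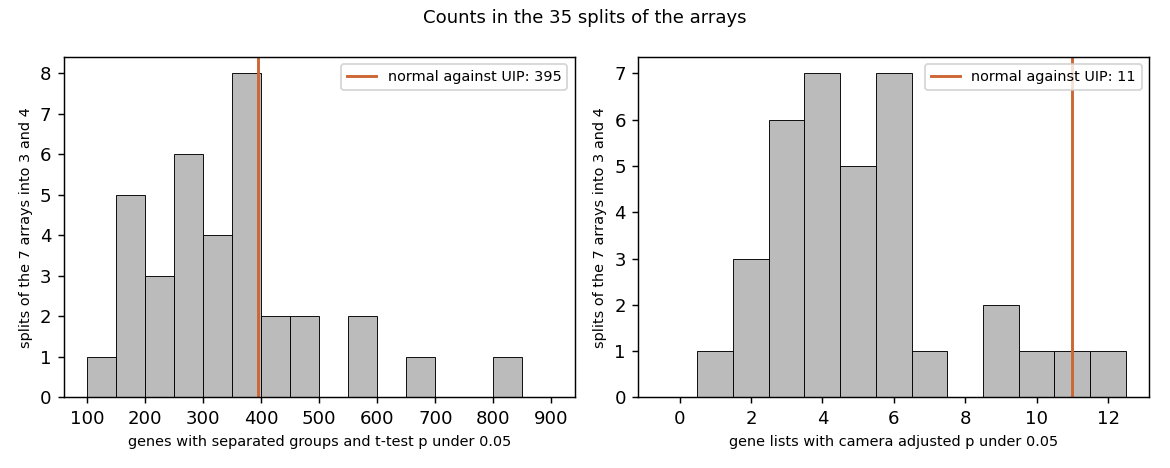
Number of genes with separated groups and the methods' t-test p under 0.05 (left) and number of gene lists called by camera (right), on the horizontal axes, over the 35 splits of the 7 arrays into 3 and 4, with the number of splits on the vertical axes. Orange lines mark the normal and UIP split, with 395 genes and 11 lists.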

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

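The tests of print lots and of single arrays as explanations and the count of splits for genes past the adjusted threshold were chosen only after the results were seen, although leaving out each array in turn was planned. The other splits and the macrophage gene test were written down before.

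Chance was not excluded for the count of genes with separated groups or for the count of lists called. For genes past limma's adjusted threshold the real count was 0 (551 at an unadjusted p under 0.05, 346 without normal replicate 2; 474 with the t-test and 366 with its Welch form), so 35 of the 35 splits gave as many whatever their values, and this count decides nothing about chance. The highest other split gave 3 genes, and it was the one that follows the print lots, with normal replicate 1 and UIP replicates 3 and 4 together; with the lot as a block the real count stayed 0. For separated groups with a t-test p under 0.05, 9 of the 35 splits gave at least 395 genes, and the highest other count was 842, from normal replicates 1 and 2 with UIP replicate 2. The split along print lots gave 678, and with the lot as a block the real count was 524. For gene lists called by camera, 2 of the 35 splits gave at least 11, and the highest other count was 12, from normal replicate 3 with UIP replicates 3 and 4.

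Leukocyte receptor genes were lower in UIP, with a list mean of -0.61 (-0.39 without normal replicate 2; adjusted p = 0.000338, and adjusted p = 0.161 with an estimated correlation). The print lot as the whole cause is argued against, because with the lot as a block the list's array means differed by -0.62 (SE over arrays 0.13, 95% interval within 0.36 of it), although in lot B, which has 1 normal array, the mean of -0.39 was not past the threshold (adjusted p = 0.114). Macrophages carried over into the normal cultures may be a source and cannot be told apart from a difference between the fibroblasts. Over 22 tested of 28 macrophage genes on the array, chosen from outside the fixed lists, the median log2 difference was -0.18, with 16 of 22 lower in UIP. Its 95% bootstrap interval over genes, -0.57 to -0.04, was too wide to decide. That interval reflects the spread between genes and not between cultures, so it does not test a group difference of these genes. The most abundant of these did not move one way: GPNMB had a log2 intensity of 10.16 in normal and 11.67 in UIP, PLEK 10.11 in normal and 10.06 in UIP and ACP5 9.99 in normal and 9.24 in UIP, and 13 of the 22 were above threshold on all 4 UIP arrays. A difference between UIP and normal fibroblasts themselves stays open, as untested.

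Cell cycle genes differed by -0.62 on average, lower in UIP. Without normal replicate 1 the mean was -0.14 (without normal replicate 3, -0.94), so a single fast-growing culture is a candidate explanation for most of it. The other arrays of its lot did not share its level: UIP replicates 3 and 4 had list means of -0.07 and -0.62, against 1.29 in normal replicate 1. The list mean of normal replicate 1 lay 1.37 from the nearest array of its lot, and the other 6 arrays spanned 0.68. Normal replicate 1 was singled out because it stood apart from every other array. A gap above that span followed from this choice whatever its lot, so the gap is no separate test of the lot. A difference in growth between UIP and normal cultures stays open, as untested.

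Interferon genes differed by -0.57 on average, lower in UIP. Without normal replicate 2 the mean was 0.000772 (without normal replicate 3, -0.92), which is consistent with that single culture as the source. The other arrays of its lot did not share its level: normal replicate 3 and UIP replicates 1 and 2 had list means of -0.31, -0.24 and -0.29, against 1.43 in normal replicate 2. The list mean of normal replicate 2 lay 1.66 from the nearest array of its lot, and the other 6 arrays spanned 0.14. A gap above that span is no separate test of the lot, because normal replicate 2 was singled out for standing apart from every other array. That array also had the highest leukocyte list mean (0.53), so an interferon response of its fibroblasts and cells of another type in that culture both stay open, as untested.

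In 11 of 88 values tested, 1 UIP array lay far from the other 3, where chance gives about 1 in 20 (4.40), and 7 of the 11 were UIP replicate 4. That array is the 1 whose header marks a rescan, and it had 149 poor spots, against 67 to 115 on the others; whether this sets it apart was not tested. KANK1 had a log2 intensity of 8.37 in UIP replicate 4 against 8.20 to 8.23 in the other UIP arrays, a gap of 0.865 of the range. FGFR2 stood at 4.82 in UIP replicate 4 against 4.30 to 4.33 in the other UIP arrays, a gap of 0.940 of the range. SLC2A11 stood at 10.35 in UIP replicate 1 against 8.30 to 8.60 in the other UIP arrays, a gap of 0.855 of the range. MSR1, under threshold on every UIP array, stood at 3.41 in UIP replicate 3 against 3.63 to 3.67 in the other UIP arrays, a gap of 0.857 of the range. For FZD7 the values were 11.06 in UIP replicate 4 against 11.67 to 11.75 in the other UIP arrays, a gap of 0.887 of the range. For SOD2 they were 4.13 in UIP replicate 4 against 4.66 to 4.73 in the other UIP arrays, a gap of 0.878 of the range. TYROBP had 5.43 in UIP replicate 4 against 2.91 to 3.21 in the other UIP arrays, a gap of 0.880 of the range. SYNPO2 had 12.66 in UIP replicate 2 against 11.07 to 11.31 in the other UIP arrays, a gap of 0.848 of the range. ADIRF had 8.10 in UIP replicate 4 against 9.43 to 9.67 in the other UIP arrays, a gap of 0.849 of the range. The mean of the collagen and matrix list was -0.50 in UIP replicate 2 against 0.35 to 0.50 in the other UIP arrays, a gap of 0.854 of the range. The mean of the TGF-beta and BMP list was 0.23 in UIP replicate 4 against 0.07 to 0.09 in the other UIP arrays, a gap of 0.876 of the range.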

How the results depend on the processing

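The settings listed under the processing of the data as chosen after the data were examined were added only after the results were seen. The other alternatives were planned. Over 36 alternatives, 7 of which leave out 1 array each, 0 of 1716 values of the 67 named genes moved past the adjusted threshold, 1707 kept their direction and 9 reversed. For the 11 called lists, 241 of 308 values kept call and direction, 60 lost the call and 7 reversed. WNT5A stayed higher in UIP, by 0.63 to 1.44 (adjusted p 0.185 to 1; 0.87 to 1.08 with 1 array left out). The number of genes changed was 0 with each array left out and in every limma alternative, and 474 with the t-test and 366 with its Welch form without adjustment, because these counts are unadjusted. The number of lists called was 7 with array weights, 0 with an estimated correlation and 0 with fry, and 6 to 13 with 1 array left out (6 without normal replicate 1, 7 without normal replicate 2). Separated genes with a t-test p under 0.05 numbered 297 to 647 with 1 array left out, the highest without normal replicate 3. COL1A1 reversed with cyclic loess (-0.00427), with array weights (-0.0571) and without normal replicate 1 (-0.115) or UIP replicate 3 (-0.0232), over a range of -0.115 to 0.143 with 1 array left out. SREBF1 reversed with its brightest probe alone (-0.22) and was at 0.13 without normal replicate 2. Without normal replicate 2 the interferon list was at 0.000772 and the cytokine list at 0.0284, in ranges of -0.92 to 0.000772 and -0.85 to 0.0284 with 1 array left out. Among alternatives added later, fits within lot A called 5 lists, 1 up and 4 down. Some probes had no value on an array in 46 of the 358 genes with several probes; with the probe levels aligned before averaging, another alternative added later, 11 lists were called and SREBF1 was at 0.33. Within lot A COL1A1 reversed to -0.22, and within lot B, with its 1 normal array, the cytokine list reversed to 0.42. With normal replicates 1 and 2 left out together 5 lists were called, 0 up and 5 down and 3 of them among the 11, so all 6 calls of lists higher in UIP were lost, and PSMB9 (0.22), VLDLR (-0.0358), COL1A1 (-0.20) and the cell cycle (0.0575), interferon (0.0785), collagen (-0.0459) and TGF-beta (-0.0393) lists reversed. Over all settings the lists' adjusted p was 4.08e-19 to 0.837 for cell cycle, 2.19e-08 to 0.914 for interferon, 2.07e-05 to 0.161 for leukocyte, 2.51e-08 to 0.837 for collagen, 3.89e-06 to 0.312 for contractile, 0.00973 to 0.312 for smooth muscle, 0.00247 to 0.917 for growth factor, 0.00426 to 0.837 for Wnt, 0.000166 to 0.917 for TGF-beta, 8.80e-06 to 0.945 for cytokine and 0.0252 to 0.312 for lipid-storing genes. Apart from the reason given for the t-test counts, the cause was not tested. Normexp on separate signal and background was planned and not run, because the files give a background-subtracted intensity; normexp with negative controls was run in its place. The median of all genes shifted by 0.01, 0.01 and -0.01 with quantile, median and cyclic loess scaling. Signal over background, with array medians 22.2 to 32.5 times the negative controls, limits genes near the floor of 2.91 (log2), such as FGFR2, MSR1 and HCLS1, to bounds on their folds.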

Other observations

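The genes named in the next paragraph and the test of the spread between arrays were chosen only after the results were seen.

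Outside the fixed lists, 10 genes were taken from the largest differences with non-overlapping groups and an unadjusted p under 0.05, and none passed the adjusted threshold (0.504 to 0.787). Higher in UIP were WFDC1, a secreted protein with a protease inhibitor fold, at 4.96 ± 2.27 (SD, n = 3) in normal and 9.18 ± 1.08 (SD, n = 4) in UIP on the log2 scale and above threshold on 2 of 3 normal arrays, and PRRX2, a homeobox transcription factor of mesenchyme, at 5.56 ± 1.48 (SD, n = 3) in normal and 8.35 ± 0.55 (SD, n = 4) in UIP. LRRC32, a surface protein that docks latent TGF-beta, differed by 1.99 ± 0.42 (log2 difference and its SE) and CTSH, a lysosomal protease, by 1.83 ± 0.47, while CHRDL2, a BMP antagonist, was above threshold on 2 of 3 normal and 4 of 4 UIP arrays. Lower in UIP were SERPINB2, an inhibitor of plasminogen activators, at 9.64 ± 0.50 (SD, n = 3) in normal and 5.82 ± 1.67 (SD, n = 4) in UIP and above threshold on 3 of 4 UIP arrays, and VAMP8, a protein of vesicle fusion, at 9.11 ± 0.19 (SD, n = 3) in normal and 5.94 ± 1.66 (SD, n = 4) in UIP. TFPI2, a protease inhibitor, differed by -1.87 ± 0.47 and LGMN, a lysosomal protease, by -2.33 ± 0.72, while CD48, a leukocyte surface protein, was above threshold on 3 of 3 normal and 0 of 4 UIP arrays. Within print lots PRRX2 differed by 2.04 in lot A and 4.32 in lot B, VAMP8 by -4.47 in lot A and -1.97 in lot B, and CHRDL2 by 0.62 in lot A, with the 1 normal array of lot B at the floor. CD48 stood at 8.07 in normal replicate 2 and at 3.73 and 5.38 in normal replicates 1 and 3.

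Normal arrays lay further apart than UIP arrays, with mean pairwise distances of 0.660 and 0.582 on the log2 scale. A wider spread of expression profiles in the normal group was a possible explanation, but 9 of the 35 splits gave a difference at least as large as the real 0.0773 (highest other 0.193), so a wider spread was not shown.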
